A study of Mus musculus with 8 samples.

How the data were processed

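The 8 ATAC-seq samples fall into 4 groups of 2 replicates (BKMFNV, BKMS17, BKMS2 and KFNV), and the deposited files used here are 4 peak lists, 1 per group, whose names say that they are merged. The submitters' processing notes name Bowtie2, SAMtools, bedtools and MACS2 and the mouse build mm10; their versions, settings and the step at which replicates were merged are not given in the sources used here. Whether reads were shifted for the Tn5 insertion offset or filtered for duplicates is likewise not given. A missing shift would move summits by a few bases, far less than the windows used, while duplicates would raise pileups.

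Each list is in the 10-column form MACS2 writes. The authors' fold enrichment at each summit is the fragment pileup plus 1 over the background plus 1, within the same list. The deposited -log10 p of each peak comes from the authors' peak caller, and the deposited score is the -log10 q times 10 to the whole number below. The deposited summit offset is the distance in bp from the interval start. The lists stop at a q of 0.05. The lists carry no library totals, so a peak missing from a list can be a weaker signal, a shallower library or a signal just under the authors' threshold. For that reason fold and p were used to rank peaks within a list, and differences between lists were described by counts of peaks.

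Sub-peaks of 1 interval were counted once, with the summit of the highest -log10 p, on the 19 autosomes, X and Y. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Shares have Wilson 95% intervals. The 4 comparisons, the named-gene rule, the gene lists and the alternatives were fixed before the data were examined, except where a test is said to have been added. For relative depth, the pileup and background at each summit were solved from the fold and the -log10 p under MACS2's Poisson model with a tolerance of 0.002 on -log10 p. The median of the lowest 1% of backgrounds in each list was taken as its genome background. All but 2 sub-peaks per list could be solved.

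Genes were taken from a RefSeq table of 21883 protein-coding gene intervals on the build GRCm38 (mm10). It was used without strand, transcription start sites, exons or sequence, which changed 3 planned steps. Peaks were assigned to the nearest gene interval within 100 kb in place of the nearest start site. Positions were described as within 1 kb of either gene end, inside a gene or between genes, so exons, introns and UTRs are not told apart. The loci of the transduced factors were measured over the gene interval in place of coding exons. The planned motif counts need the genome sequence and were not run.

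The 13 gene lists (275 genes, all matched) were neural stem and progenitor, neuronal differentiation, fibroblast and mesenchymal, AP-1 and YAP target, pluripotency, epithelial, endoderm, endothelial, macrophage, skeletal and cardiac muscle, neural crest and Schwann, Myc target and ribosome biogenesis, and housekeeping. For each pair, the share of 1-list-only peaks near a list's members that were in the first-named list was placed among 10000 random gene lists of the same size, matched on the number of peaks near each gene in 5 bins. A list outside the central 95% of random lists was counted as outside. This describes the lists and does not test the conditions.

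Genes were named by a rule. On each side of a pair, genes were ranked by the number of 1-list-only peaks among the strongest 10% of that list by fold, ties by the highest fold, and the first 10 genes with no such peak of the other side could be named. Up to 8 members per gene list and pair with the largest difference in 1-list-only peaks, the 5 transduced factors, and the 3 strongest 1-list-only peaks of each side could also be named. Named members are therefore those that differ most, and some genes the rule takes are not reported here.

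An added test asked whether the pileup of a 1-list-only peak exceeded the highest pileup that the other list could hold without a call, at the backgrounds of both lists (one-sided exact binomial test, Benjamini-Hochberg adjusted, threshold 0.05). It concerns the merged libraries and their counting error, not the conditions. The alternatives were a minimum -log10 q of 5, lists trimmed to the same number of peaks by -log10 p, the strongest 50% of a list against the complete other list, an overlap of at least 50% of both peaks, summits within 200 bp, assignment within 25 kb or at gene ends only, and a gene-end window of 2.5 kb. Added after the data were seen were lists trimmed to their 5000 to 30000 strongest peaks, pileups thinned to the shallowest list over 20 repeats, ranking by fold, gene lists without the transduced factors, and classes of regions over all 4 lists.

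Pileup recovery, the overlap rules, the placing of gene lists, the counting-error test and thinning were tested on simulated data, and the other steps were not. The pileup was recovered in 2105 of 2106 simulated peaks, and each of the 3 overlap rules matched a direct count for 1000 of 1000 simulated intervals. Of 1000 simulated gene lists with no tilt, 44 (4.4%) lay outside the central 95%, and of 1000 with a 2-fold tilt 672 (67.2%) did. The counting-error test recovered between 0 (KFNV against BKMFNV) and 46 (BKMFNV against KFNV) of 200 simulated peaks with changed pileups, and in the latter made 10 false calls. That simulation took the observed pileup of each called peak as its true mean and counted shares over all peaks, called again or not. Its shares of 1-list-only peaks without change are therefore biased low and do not give the split to expect without change. The unadjusted pass counts among those simulated peaks likewise give no rate to expect. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.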

Results

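Open chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in mouse embryonic fibroblasts carrying a Sox2-GFP reporter. The fibroblasts received doxycycline-inducible lentiviruses for a set of transcription factors and were collected at day 4 after the switch to neural stem cell medium with 1 µg/mL doxycycline, 50000 cells per library. The 8 samples formed 4 groups of 2 replicates. BKMFNV cells received Brn4 (gene Pou3f4), Klf4, c-Myc and an engineered form of Sox17 that the labels call eSox17FNV. BKMS17 cells received wild-type Sox17 in its place, and BKMS2 cells received Sox2. KFNV cells received only Klf4 and eSox17FNV. Brn4 is a POU factor of neural development, Klf4 a zinc-finger factor used in reprogramming, c-Myc a regulator of cell growth, Sox2 a factor of neural stem and pluripotent cells, and Sox17 a factor of endoderm and endothelium. The comparisons address how the choice of Sox factor, and the presence of Brn4 and c-Myc, went with the accessible regions early in the conversion of fibroblasts in neural stem cell medium. The files hold 1 merged peak list per group, so there are no replicates within a comparison and no p-value across conditions is given. The counts describe these lists, and whether the factor cocktails differ was not tested. Wilson 95% intervals cover counting error only.

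The BKMFNV list held 48619 peaks with a median width of 599 bp covering 35.9 Mb, and the BKMS2 list 56844 peaks of 641 bp covering 43.7 Mb. The BKMS17 list held 61451 peaks of 654 bp covering 48.0 Mb. The KFNV list was the longest, with 85830 peaks of 748 bp covering 74.6 Mb. The median fold enrichment, as the authors' peak caller gave it at each peak's summit, was 3.36 in BKMFNV, 3.24 in BKMS17, 3.32 in BKMS2 and 3.08 in KFNV. The pileup recovered from these values was 21 fragments at the median BKMFNV summit, 23 in BKMS17 and BKMS2 and 31 in KFNV. The genome-wide background, a measure of relative depth, was 4.22 in BKMFNV, 4.87 in BKMS17 (1.15 times), 4.58 in BKMS2 (1.09 times) and 7.27 in KFNV (1.72 times). The 4 lists stood in the same order by length and by background. Library totals were not used here.

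The loci of the transduced factors were described first, because integrated cDNA copies add fragments over the endogenous gene and so check the labels. At Sox17 (mm10 chromosome 1, 4490928 to 4497426), a single peak covered 1577 bp of the gene in BKMFNV, 1588 bp in BKMS17 and 1572 bp in KFNV. Its fold stood at percentile 90.9, 97.0 and 90.2 of the sub-peaks of its own list. Percentiles at the other loci are likewise among sub-peaks. In BKMS2, which received no Sox17, 2 smaller peaks covered 1147 bp and the stronger stood at percentile 65.8. At Pou3f4 (chromosome X, 110814379 to 110819108), a peak covered 999 bp in BKMFNV (percentile 95.7 of its list by fold), 974 bp in BKMS17 (98.3) and 1107 bp in BKMS2 (98.6). In KFNV, which received no Brn4, it covered 660 bp and stood at percentile 44.5. At Sox2 (chromosome 3, 34649995 to 34652461), peaks covered 1292 bp in BKMS2 against 248 bp in BKMFNV, 301 bp in BKMS17 and 713 bp in KFNV. The strongest summit inside Sox2 stood at percentile 36.6 of its list in BKMS2 and at 54.9 in KFNV, which received no Sox2. At Myc (chromosome 15, 61985341 to 61990361), covered length was 3258 bp in BKMFNV, 2057 bp in BKMS17, 2077 bp in BKMS2 and 1539 bp in KFNV, which received no c-Myc. By fold, the strongest summit inside Myc stood at percentile 16.3 in BKMFNV, 1.60 in BKMS17, 3.14 in BKMS2 and 3.31 in KFNV. Klf4 (chromosome 4, 55527137 to 55532475), present in every cocktail, had 1896 bp covered in BKMFNV, 1920 bp in BKMS17, 1488 bp in BKMS2 and 2098 bp in KFNV, at percentiles 66.1, 20.4, 30.1 and 11.6. Each of the 5 loci had its longest covered length in a list whose cocktail held the factor, which for Klf4 is every list. Every factor but Sox2 was in most or all cocktails, so this is a weak check of the labels. BKMFNV and BKMS17 both received a form of Sox17, and these loci cannot tell their labels apart. Peaks over these genes are not read as accessibility of the endogenous loci.

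**Figure D1:**
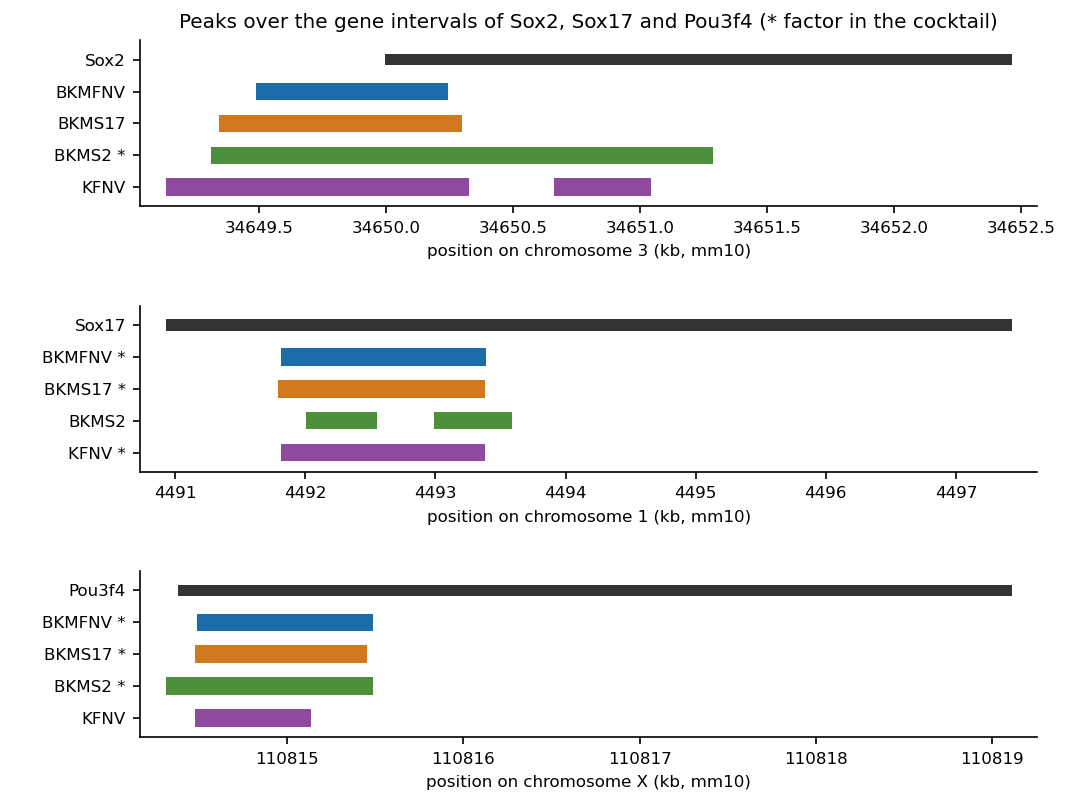
Peaks over the gene intervals of Sox2, Sox17 and Pou3f4 in the 4 lists, drawn to scale along the chromosome in kb (mm10); black bars are the gene intervals and an asterisk marks a list whose cocktail held the factor. Peaks cover 1292 bp of Sox2 in BKMS2, and the Sox17 peak spans 1577 bp in BKMFNV, 1588 bp in BKMS17 and 1572 bp in KFNV against 2 smaller peaks in BKMS2.

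The comparison of BKMFNV with BKMS17 sets the engineered Sox17 beside wild-type Sox17. Near neural stem and progenitor genes, 31 peaks were in the BKMFNV list only and 51 in the BKMS17 list only. With both lists trimmed to the same number of peaks the counts were 44 against 28. The BKMFNV share of 1-list-only peaks near any gene also rose then, from 28.8% to 49.6%. The neural stem list lay above the random median in both settings, by 9.23 and 11.8 points. The members differed in direction: the forebrain regulators Emx2 (0 in BKMFNV only against 3 in BKMS17 only) and Lhx2 (0 against 3) and the glutamate transporter gene Slc1a3 (0 against 5) had BKMS17-only peaks, while Pax6 (3 against 1) and Nkx2-2 (2 against 0), regulators of neural patterning, had more BKMFNV-only peaks. Near fibroblast and mesenchymal genes the counts were 31 against 94, led by the transcription factor genes Runx1 (3 against 12) and Zeb1 (1 against 7), the collagen gene Col5a1 (2 against 7) and the TGF-beta receptor gene Tgfbr2 (1 against 6). The neuronal microtubule gene Map2 had 0 BKMFNV-only and 6 BKMS17-only peaks. Near pluripotency genes the counts were 13 against 15, with Esrrb at 1 against 5 and Sall4 at 3 against 2, and in trimmed lists 15 against 6. In the whole lists, 8823 of 48619 BKMFNV peaks (18.1%, 17.8 to 18.5) overlapped no BKMS17 peak, and 22096 of 61451 BKMS17 peaks (36.0%, 35.6 to 36.3) overlapped no BKMFNV peak. Among 1-list-only peaks assigned to any gene, 28.8% were in BKMFNV, and 0 of the 13 gene lists fell outside the central 95% of 10000 random gene lists matched on peak number. The neural stem list stood at percentile 97.2, and outside the central 95% at percentile 99.7 when peaks were assigned within 25 kb (27 against 34), while the pluripotency list stood at 97.1. The other lists lay between percentiles 16.9 and 84.4: endoderm 20 against 39, endothelial 12 against 32, epithelial 7 against 25, neuronal differentiation 18 against 50, neural crest and Schwann 10 against 19, AP-1 and YAP target 8 against 14, Myc target and ribosome biogenesis 3 against 9, macrophage 4 against 6, muscle 5 against 13 and housekeeping 5 against 8. The strongest BKMS17-only peaks by fold lay near Nudt12 (chromosome 17, 59076759 to 59077125, fold 7.33), near Crisp4, a sperm protein gene (chromosome 1, 18158744 to 18159778, fold 6.65), and inside Cpe, the carboxypeptidase E gene (chromosome 8, 64596971 to 64597310, fold 6.48). The strongest BKMFNV-only peaks lay inside Mrc1, the macrophage mannose receptor gene (chromosome 2, 14295463 to 14295711, fold 5.75), and 83384 bp from Akr1d1, a steroid reductase gene (chromosome 6, 37658083 to 37658568, fold 5.75). The third was on chromosome 6 (109229509 to 109230479, fold 5.72), 347289 bp from the nearest gene, Gm6749. With both lists trimmed to the same number of peaks the split was 12128 BKMFNV-only against 12663 BKMS17-only. The larger count then also lay with BKMFNV for neuronal (30 against 25), endoderm (29 against 23), AP-1 and YAP target (14 against 9), neural crest and Schwann (15 against 12) and housekeeping genes (6 against 3). Of these only the neuronal list changed its side of the random median, from -2.10 to 5.39 points. None of these peaks exceeded, beyond counting error, the highest pileup the other list could hold uncalled (one-sided exact binomial test, Benjamini-Hochberg). That says little, since the test recovered 16 (BKMFNV side) and 18 (BKMS17 side) of 200 simulated changes. Unadjusted, 261 of 8823 BKMFNV-only and 675 of 22096 BKMS17-only peaks passed. In simulated unchanged pileups 265 of 2961 and 333 of 7029 did, which sets no rate to expect without change. The simulated 1-list-only shares were 6.12% for BKMFNV and 11.5% for BKMS17, biased low by the setting of the simulation.

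The comparison of BKMFNV with BKMS2 sets the engineered Sox17 beside Sox2. Near fibroblast and mesenchymal genes, 26 peaks were in the BKMFNV list only and 90 in the BKMS2 list only, a BKMFNV share of 22.4% at percentile 0.68 of random gene lists (median 34.6%). The matrix genes Col5a1 (1 against 8) and Fbn1 (1 against 8), the surface marker gene Thy1 (1 against 7), the metalloproteinase gene Mmp2 (0 against 5) and the mesenchymal regulator genes Zeb1 (0 against 4) and Snai1 (0 against 4) led this list. Near epithelial genes the counts were 9 against 37 (percentile 1.91), with the keratin gene Krt19 at 0 against 4, the protease gene St14 at 0 against 4 and the epithelial regulator Grhl3 at 1 against 5. Near muscle genes the counts were 1 against 17 (percentile 0.79), with Mef2c at 0 against 6 and Tbx5 at 0 against 4, both transcription factor genes. These 3 of the 13 lists lay outside the central 95% of random lists in this pair, and 5 of 52 did over all 4 pairs, where 2.6 are expected by chance. Near neuronal genes the counts were 32 against 36 (percentile 96.7), with the synaptic vesicle gene Syt1 at 5 against 3, and near neural stem and progenitor genes 27 against 40 (percentile 83.8), with Ptprz1 at 3 against 0, Pax6 at 3 against 1 and the Notch ligand gene Dll1 at 0 against 5. The remaining lists lay between percentiles 26.4 and 77.9: endoderm 25 against 44, endothelial 17 against 40, pluripotency 12 against 17, neural crest and Schwann 11 against 18, AP-1 and YAP target 10 against 22, Myc target and ribosome biogenesis 5 against 7, macrophage 6 against 6 and housekeeping 5 against 9. In the whole lists, 10353 of 48619 BKMFNV peaks (21.3%, 20.9 to 21.7) overlapped no BKMS2 peak and 18805 of 56844 BKMS2 peaks (33.1%, 32.7 to 33.5) overlapped no BKMFNV peak. The BKMS2-only peak with the highest fold lay inside Myo3a, a myosin gene of sensory hair cells (chromosome 2, 22589522 to 22590012, fold 14.4, pileup 101), and was the only peak beyond counting error in either direction (adjusted p = 6.01e-12, one-sided exact binomial test on these merged libraries). The peak list does not show whether this signal is accessible chromatin, a lentiviral integration site or an amplified fragment. The next BKMS2-only folds were 6.80 at a peak 510635 bp from the cadherin gene Fat1 (chromosome 8, 44421972 to 44422828) and 6.75 inside the synaptic scaffold gene Dlg2 (chromosome 7, 92103003 to 92103364). Among BKMFNV-only peaks the highest folds were 5.97 at a peak 267276 bp from Reg3g (chromosome 6, 78735139 to 78736424), 5.94 near Gm19802 (chromosome 10, 81997164 to 81997425) and 5.75 near Akr1d1. With both lists trimmed to the same number of peaks the split was 12625 BKMFNV-only against 12969 BKMS2-only, and 0 of the 13 gene lists lay outside the central 95% (fibroblast 39 against 65, percentile 2.65; epithelial 12 against 25, percentile 3.71; muscle 3 against 10, percentile 4.50). In trimmed lists the larger count lay with BKMFNV near neural stem (41 against 26), neuronal (38 against 26) and pluripotency genes (14 against 12). The same held near AP-1 and YAP target (12 against 7) and Myc target genes (6 against 4). The BKMFNV share of 1-list-only peaks near any gene also rose then, from 34.96% to 49.06%. Of these lists only AP-1 and YAP target changed its side of the random median, from -3.125 to 14.5 points. The counting-error test recovered 28 (BKMFNV side) and 8 (BKMS2 side) of 200 simulated changes, so other changes could go unseen. Unadjusted, 318 of 10353 BKMFNV-only and 721 of 18805 BKMS2-only peaks passed it. In simulated unchanged pileups 242 of 3774 and 336 of 5583 did, which sets no rate to expect without change. The simulated 1-list-only shares were 7.79% for BKMFNV and 9.86% for BKMS2, biased low by the setting of the simulation.

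The comparison of BKMS2 with BKMS17 sets Sox2 beside wild-type Sox17. Near AP-1 and YAP target genes, 16 peaks were in the BKMS2 list only and 9 in the BKMS17 list only, a BKMS2 share of 64.0% at percentile 99.2 of random lists (median 42.9%). Amotl2, a YAP-binding angiomotin gene, held 4 of these BKMS2-only peaks against 0, and Ankrd1, a YAP target, 2 against 1. The AP-1 subunit genes differed in direction: Jun and Fosl2 each had 1 against 2, while Fosb, Jund and Atf3 each had 1 against 0. Near epithelial genes the counts were 28 against 18 (60.9%, percentile 98.3), with Krt19 at 4 against 1, the cadherin gene Cdh3 at 4 against 2, the plakoglobin gene Jup at 3 against 1, and the E-cadherin gene Cdh1 in the opposite direction at 0 against 2. These 2 of the 13 lists lay outside the central 95%, and both also did with the lists trimmed to the same number of peaks (17 against 5, percentile 99.9, and 29 against 12, percentile 99.5). Near endoderm genes the counts were 32 against 31, with Gata4 at 5 against 1 and the collagen gene Col4a2 at 5 against 1, while Eomes had 0 against 3 and Col4a1 2 against 5. Near fibroblast genes they were 55 against 56, with Thy1 at 4 against 0 and Mmp2 at 4 against 0, while Runx1 had 2 against 9 and Tgfbr2 0 against 4. Near neuronal genes they were 24 against 50 (percentile 5.47), of which Myt1l, a neuronal zinc-finger gene, held 1 and 5. The other lists lay between percentiles 50.0 and 94.6: neural stem and progenitor 32 against 41, endothelial 26 against 23, pluripotency 14 against 11, neural crest and Schwann 16 against 18, muscle 15 against 8, Myc target and ribosome biogenesis 6 against 8, macrophage 6 against 8 and housekeeping 9 against 7. In the whole lists, 12995 of 56844 BKMS2 peaks (22.9%, 22.5 to 23.2) overlapped no BKMS17 peak and 17832 of 61451 BKMS17 peaks (29.0%, 28.7 to 29.4) overlapped no BKMS2 peak. The Myo3a peak was the strongest BKMS2-only peak and the only peak beyond counting error (adjusted p = 3.43e-14, one-sided exact binomial test), with the same doubt over an integration site or amplified fragment, followed by peaks near H2-M10.5 (chromosome 17, 36788804 to 36789113, fold 6.27) and inside the protocadherin gene Pcdh15 (chromosome 10, 73216067 to 73216936, fold 5.91). The strongest BKMS17-only peaks lay near Crisp4 (fold 6.65), inside Fam189a2 (chromosome 19, 24023591 to 24024776, fold 6.53) and inside Cpe (fold 6.48), and a BKMS17-only peak of fold 5.96 lay 43106 bp from the neural crest gene Pax3 (chromosome 1, 78057984 to 78058618). With both lists trimmed to the same number of peaks the split was 14485 against 14778. The larger count then lay with BKMS2 near neural stem (37 against 31), fibroblast (59 against 45) and neural crest and Schwann genes (19 against 17). The counting-error test recovered 13 (BKMS2 side) and 14 (BKMS17 side) of 200 simulated changes, so other changes could go unseen. Unadjusted, 506 of 12995 BKMS2-only and 758 of 17832 BKMS17-only peaks passed it. In simulated unchanged pileups 354 of 3914 and 409 of 6334 did, which sets no rate to expect without change. The simulated 1-list-only shares were 6.91% for BKMS2 and 10.3% for BKMS17, biased low by the setting of the simulation.

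The comparison of KFNV with BKMFNV sets Klf4 and eSox17FNV alone beside the same factors with Brn4 and c-Myc. Near fibroblast and mesenchymal genes, 216 peaks were in the KFNV list only and 20 in the BKMFNV list only. The osteoblast and mesenchymal regulator Runx2 had 22 against 1, Runx1 20 against 0, Zeb2 15 against 0 and Fbn1 13 against 0. Near neural stem and progenitor genes the counts were 119 against 21, with the growth factor receptor gene Egfr at 16 against 1, Slc1a3 at 13 against 0 and Lhx2 at 8 against 0, and near neuronal genes 85 against 21, with Ncam1 at 13 against 2 and Map2 at 12 against 1. Among 1-list-only peaks assigned to any gene, 86.8% were in KFNV, and 0 of the 13 lists lay outside the central 95% of random lists. The fibroblast list stood at percentile 94.0 and the neuronal list at 4.47, with the others between 22.8 and 64.2: endoderm 85 against 12, endothelial 67 against 11, epithelial 45 against 6, neural crest and Schwann 40 against 5, AP-1 and YAP target 39 against 6, pluripotency 39 against 7, macrophage 27 against 3, muscle 23 against 4, Myc target and ribosome biogenesis 17 against 2 and housekeeping 12 against 3. Among KFNV-only peaks within the strongest 10% of the list, Dlg2, Map2, the olfactomedin gene Olfm3, Edil3 and the teneurin gene Tenm3 held 3 each with no such BKMFNV-only peak. The guidance gene Sema3a and the collagen gene Col3a1 held 2 each, with highest folds of 6.77 and 6.29. In the whole lists, 44912 of 85830 KFNV peaks (52.3%, 52.0 to 52.7) overlapped no BKMFNV peak and 6899 of 48619 BKMFNV peaks (14.2%, 13.9 to 14.5) overlapped no KFNV peak. The strongest KFNV-only peaks lay inside the glycosyltransferase gene Galnt13 (chromosome 2, 54567296 to 54568380, fold 7.14), 209772 bp from Mzt1 (chromosome 14, 98824340 to 98825225, fold 6.90) and inside Smarcal1 (chromosome 1, 72564317 to 72565017, fold 6.78). The strongest BKMFNV-only peaks lay inside Mgat4c (chromosome 10, 101709948 to 101710881, fold 6.28), 267276 bp from Reg3g (fold 5.97) and 133734 bp from Cd47 (chromosome 16, 50046120 to 50046449, fold 5.75). With both lists trimmed to the same number of peaks the split was 14562 KFNV-only against 13688 BKMFNV-only, and 3 lists lay outside the central 95%: fibroblast 66 against 38 (percentile 97.8), pluripotency 6 against 20 (percentile 1.18) and Myc target and ribosome biogenesis 2 against 9 (percentile 1.52, on the opposite side of the random median from the complete lists). In trimmed lists the larger count lay with BKMFNV in every list but fibroblast, as for neural stem (37 against 47) and neuronal genes (36 against 43). Of the lists leaning to BKMFNV, only pluripotency and Myc target lay outside the central 95% of random lists. No peak passed the counting-error test after adjustment. On the KFNV side this decides nothing, since the test recovered 0 of 200 simulated changes there. On the BKMFNV side it recovered 46 of 200. Unadjusted, 2606 of 44912 KFNV-only and 1135 of 6899 BKMFNV-only peaks passed. In simulated unchanged pileups 398 of 16122 and 206 of 858 did, which sets no rate to expect without change. The simulated 1-list-only shares were 18.8% for KFNV and 1.77% for BKMFNV, biased low by the setting of the simulation.

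**Figure D2:**
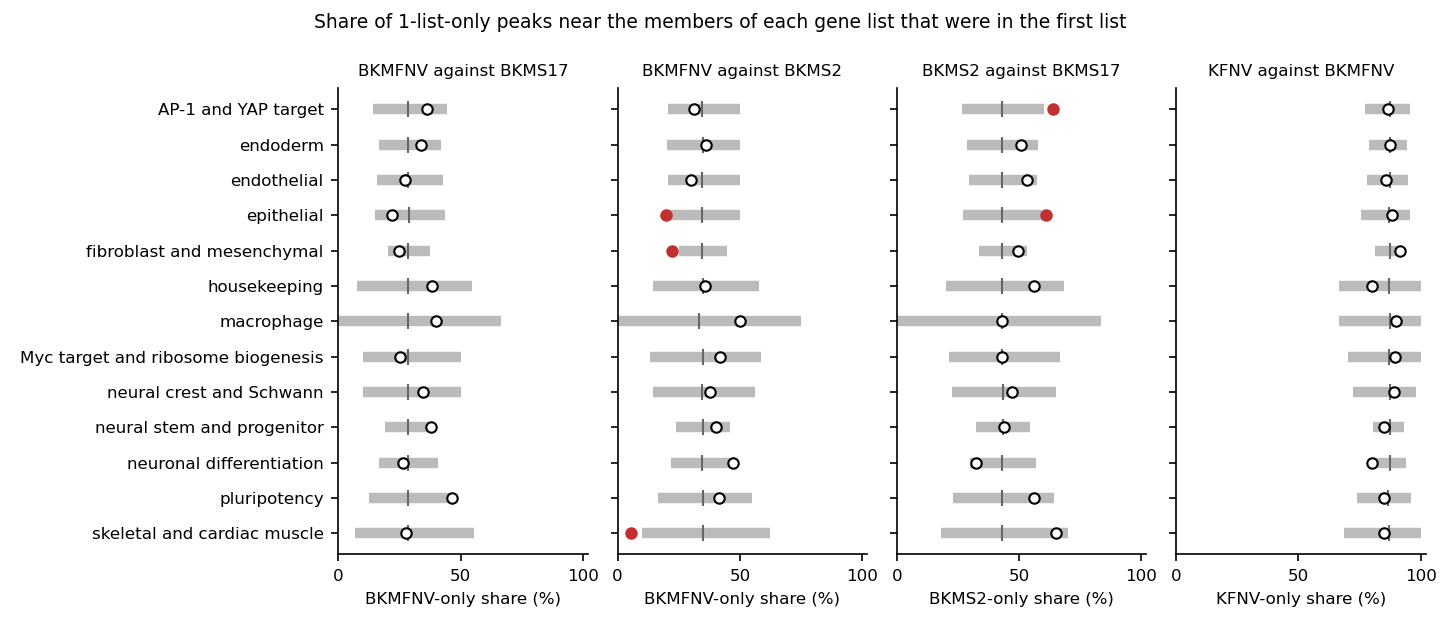
Share of 1-list-only peaks near the members of each of 13 gene lists that were in the first-named list, in percent, for the 4 pairs. Circles are the observed shares, grey bars the central 95% and ticks the median of 10000 random gene lists matched on peak number; filled circles lie outside the bar, as for fibroblast (22.4%), epithelial (19.6%) and muscle (5.56%) genes in BKMFNV against BKMS2.

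To ask whether the list of the engineered Sox17 shared more with that of Sox2 or of wild-type Sox17, the 3 four-factor lists were merged into 79785 regions. All 3 lists held 35142 of them (44.0%). BKMFNV shared 3964 regions (4.97%) with BKMS17 and not BKMS2, and 2553 regions (3.20%) with BKMS2 and not BKMS17, a difference of 1411 regions. With each list trimmed to the length of the shortest, these were 4173 and 3749 regions, a difference of 424, and the difference kept its sign in the 3 alternatives run. BKMS17 and BKMS2 shared 8085 regions (10.1%) that BKMFNV lacked. Regions in 1 list alone numbered 13723 for BKMS17, 10291 for BKMS2 and 6027 for BKMFNV, in the order of the lists' lengths. With KFNV added, 34355 of 104750 regions (32.8%) were in all 4 lists and 26326 (25.1%) in KFNV alone.

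**Figure D3:**
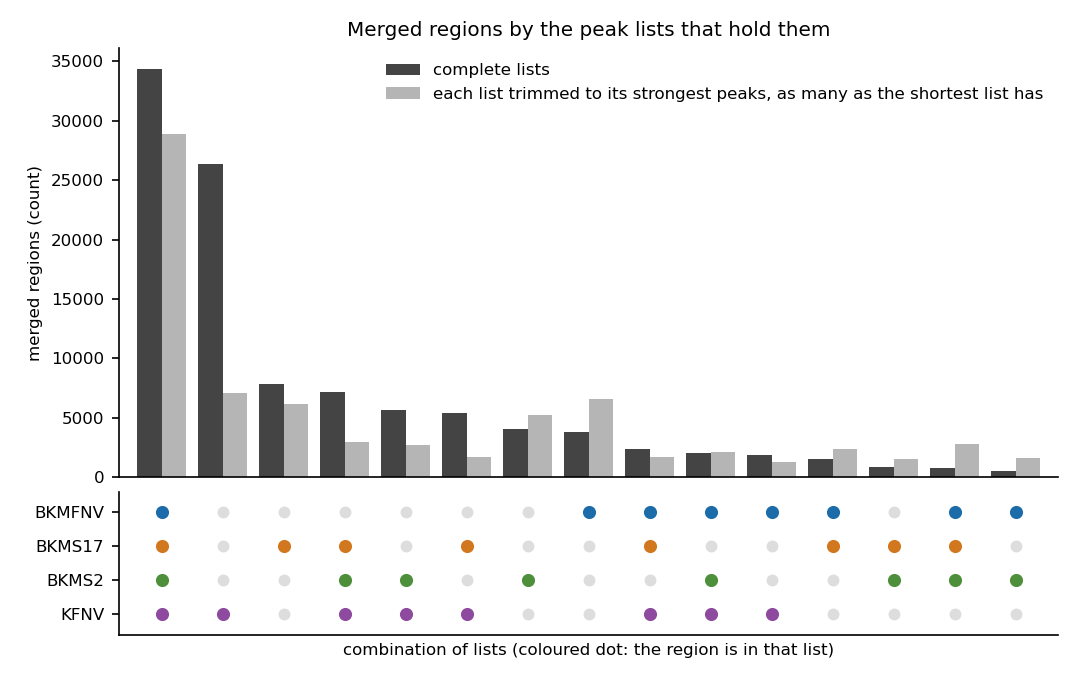
Number of merged regions in each combination of the 4 peak lists, given by the coloured dots under each pair of bars, for the complete lists (dark bars) and for lists trimmed to the length of the shortest (light bars). All 4 complete lists hold 34355 regions and KFNV alone holds 26326.

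Peaks near gene ends were mostly shared between lists. Summits within 1 kb of either end of a protein-coding gene interval made up 12018 of BKMFNV peaks (24.7%), 12504 of BKMS17 peaks (20.3%), 12404 of BKMS2 peaks (21.8%) and 13198 of KFNV peaks (15.4%). Summits inside genes, away from their ends, made up 38.4%, 40.5%, 39.9% and 42.5%, and summits between genes 36.9%, 39.2%, 38.3% and 42.1%. Of the BKMFNV peaks absent from BKMS17, 5.32% (4.87 to 5.80) were at gene ends against 29.0% (28.6 to 29.5) of those shared with it. Of the KFNV peaks absent from BKMFNV, 3.77% (3.60 to 3.95) were at gene ends against 28.1% (27.7 to 28.6) of those shared. With the lists trimmed to 48619 peaks each, the gene-end shares were 24.7% in BKMFNV, 24.3% in BKMS17, 24.5% in BKMS2 and 23.0% (22.6 to 23.3) in KFNV.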

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

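The counting-error test and the lists of equal length over all 4 groups were chosen only after the result was seen. No paired analysis was possible because each group has 1 merged list, which also rules out a replicate block and leaving out a replicate. The planned motif counts and their alternatives were not run, since the genome sequence was not used here. Depth limits the counts: the lists are ordered alike by length and background, and the counting-error test recovered 0 of 200 simulated changes among KFNV peaks against BKMFNV. Of 48 counts of 1-list-only peaks under alternatives, 16 stayed within 1.5 times and 32 moved; of 256 values of single gene lists, 215 kept their side of the central 95% and their direction, 10 lost and 5 gained a place outside it, 2 reversed and 24 moved. These include values at gene ends, where 1-list-only peaks are so few that the central 95% of random lists mostly spans 0 to 100% and no list can lie outside it. They also include the setting without the transduced factors. Only the endoderm (Sox17) and neural stem (Sox2) lists hold such a factor, so the other lists stay the same there but for the random draw. With all 4 lists trimmed to equal lengths, 42 of 48 counts moved, as did 41 of 44 gene-end shares of the strongest peaks. Fewer peaks enter when a list is restricted and fewer pairs match under a stricter overlap, so those shifts follow from construction; for the other shifts the cause was not tested.

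With a -log10 q of at least 5, 1-list-only peaks numbered 2837 in BKMFNV and 10982 in BKMS17, 3539 in BKMFNV and 9006 in BKMS2, 5538 in BKMS2 and 8218 in BKMS17, and 29785 in KFNV and 1581 in BKMFNV. Among the strongest 50% against the complete other list, in the same order of pairs, they were 739 and 3397, 1125 and 2574, 1203 and 2650, and 11099 and 861. With lists trimmed to the same number of peaks, 12663 BKMS17 peaks were absent from BKMFNV, 14562 KFNV peaks from BKMFNV and 13688 BKMFNV peaks from KFNV. With an overlap of at least 50% of both peaks, 17108 BKMFNV peaks were absent from BKMS17, 18118 from BKMS2 and 20240 from KFNV, and 20974 BKMS2 peaks from BKMS17. With summits within 200 bp, 10754 BKMFNV peaks were absent from KFNV. Beyond counting error, 1 BKMS2 peak remained against BKMFNV, 1 BKMS2 peak against BKMS17, and 0 on the other 6 sides. For KFNV against BKMFNV the 0 decides nothing, since the test recovered 0 of 200 simulated changes there. On the other sides it recovered from 8 (BKMS2 against BKMFNV) to 46 (BKMFNV against KFNV) of 200, so a 0 there says little.

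BKMFNV shared more regions with BKMS17 than with BKMS2 by 1411, by 701 at a -log10 q of at least 5, by 795 with summits within 200 bp and by 424 with trimmed lists. The gene-end share was 31.0% in BKMFNV, 26.0% in BKMS17, 27.8% in BKMS2 and 20.6% in KFNV within 2.5 kb, and 24.3% in BKMS17, 24.5% in BKMS2 and 23.0% in KFNV with trimmed lists. The number of gene lists outside the central 95% was 1 within 25 kb for BKMFNV against BKMS17 (0 in the complete lists). For BKMFNV against BKMS2 (3) it was 0 trimmed and 1 within 25 kb. At gene ends it was 0 for this pair and 0 for BKMS2 against BKMS17 (2), which says nothing of these lists, since the random range was 0 to 100% throughout. For KFNV against BKMFNV (0) it was 3 trimmed, 1 with summits within 200 bp and 1 within 25 kb. The fibroblast list in BKMFNV against BKMS2 reversed at gene ends (33.3 points above the random median, on 2 against 1 peaks), and the Myc target list in KFNV against BKMFNV reversed with trimmed lists (-28.9 points, 2 against 9 peaks).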

Other observations

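The tests of whether the lower depth of BKMFNV accounts for its absent peaks, and the classes of regions over all 4 lists, were chosen only after the result was seen. Total peaks near pluripotency genes numbered 45 in BKMFNV, 46 in BKMS17, 49 in BKMS2 and 77 in KFNV, beside 44213, 55037, 51555 and 75425 near all genes. The following genes were chosen after their values were seen. In the complete lists, of which KFNV is the longest, Pou5f1, which encodes Oct4, had 0 peaks in the 3 four-factor lists and 3 in KFNV. Zfp42 had 0 and 1. In lists trimmed to equal length, the pluripotency list had 2 regions in the 3 four-factor lists without KFNV and 4 in KFNV alone (percentile 45.9 of random lists). Nanog had 4 peaks in each four-factor list and 5 in KFNV, as did Tet1, and Dppa2 and Dppa4 had 0 in all 4 lists. The macrophage genes Adgre1, Lyz2 and Tyrobp had 0 in all 4 lists. Other members held peaks, and the whole macrophage list had 14 in BKMFNV, 16 in BKMS17, 14 in BKMS2 and 38 in KFNV. The muscle and neuronal regulator gene Mef2c had 12 peaks in BKMFNV, 14 in BKMS17, 18 in BKMS2 and 15 in KFNV, and Pax6 had 7, 4, 4 and 4. Krt19 had 0 in BKMFNV, 1 in BKMS17, 4 in BKMS2 and 1 in KFNV.

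With all 4 lists trimmed to 48619 peaks, 28834 regions were in all 4 lists, 7068 in KFNV alone and 2786 in the 3 four-factor lists without KFNV. Near Runx1, 0 regions were in the 3 four-factor lists without KFNV and 8 in KFNV alone, and near Runx2, Egfr, Map2 and Ncam1 0 and 5 each. The fibroblast list as a whole had 10 and 29 (percentile 38.4 of random lists), the neural stem list 9 and 21 (percentile 53.8) and the neuronal list 9 and 20 (percentile 58.7). The muscle list had 9 and 3 (percentile 94.8). By its percentile only the housekeeping list was counted as outside (97.7, on 1 and 0 regions). Its random range was 0 to 100%, so this call says nothing of that list.

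Among the 5000 strongest peaks by -log10 p, 81.6% in BKMFNV, 80.4% in BKMS17, 78.6% in BKMS2 and 70.0% (68.7 to 71.2) in KFNV lay within 1 kb of a gene end. The gap from KFNV to the nearest list was 8.66 points. It had not narrowed among 10000 peaks (BKMS2 and KFNV at 68.3% and 59.3%). It was narrower among 20000 (46.6% and 42.3%) and 30000 (34.8% and 32.3%). With pileups thinned to the shallowest list the gap was 12.7 points (65.4% in KFNV and 78.1% in BKMS2, and 31.5% and 34.9% among 30000). Thinning lowered the share among the 5000 strongest in each thinned list, with BKMS17 at 79.7%. This argues against greater depth of KFNV as the whole cause only as far as depth acts through the counts at summits. The called peaks were ranked again but not called anew, so an effect of depth on peak calling was not tested. Ranking by -log10 p is argued against too, since by fold the gap was 18.4 points (43.2% and 61.6%; 26.2% and 31.9% among 30000). Library preparation stays open, because each list is a group of its own and preparation and group cannot be told apart. As a hypothesis from the same data, the absence of Brn4 and c-Myc in KFNV may also bear on it, which was not tested.

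KFNV peaks were absent from BKMFNV (52.3%) more often than from BKMS2 (42.3%), and the lower depth of BKMFNV remains undecided as the cause. Among the 10000 strongest peaks of every list the gap was 2.02 points (28.7% and 26.7%) and among the 5000 strongest 0.4 points, while it was wider in longer lists: 28.8% and 24.9% at 20000, 29.6% and 24.7% at 30000, and 14562 and 11887 peaks at 48619. In the opposite direction, 3.54% of the strongest 50% of BKMFNV peaks were absent from KFNV against 1.31% of those of BKMS2, a gap of 2.23 points, with BKMS17 at 5.34%. At equal numbers the BKMFNV and BKMS2 shares were 37.4% and 37.0% among the 5000 strongest and 28.7% and 26.7% among the 10000 strongest. They lay further apart in longer lists, at 28.6% and 24.9% among 20000, 28.9% and 24.4% among 30000 and 28.2% and 23.3% among 48619. Lower depth is undecided here too, and library preparation and the cocktails stay open as untested.

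Peaks in 1 list only near fibroblast, epithelial and muscle genes tilted to BKMS2 against BKMFNV, at -12.2, -15.1 and -29.2 points from the random median (percentiles 0.68, 1.91 and 0.79). For unequal list length, 0 of the 3 lists were outside the central 95% of random lists after trimming, at -10.9, -16.3 and -26.9 points (percentiles 2.65, 3.71 and 4.50): the calls ended as the random range moved (for fibroblast genes its lower end from 25% to 37.4%, beside observed shares of 22.4% and 37.5%), while 0 of the 3 tilts shrank by more than 50%. Whether fewer peaks or the changed split moved the range was not tested. For assignment of distant peaks, 1 of the 3 was outside within 25 kb (percentiles 2.57, 3.10 and 1.11), again with 0 tilts shrunk by more than 50%. Neither explanation is decided by these values, the difference in Sox factor stays open as untested, and 2.6 lists of 52 are expected outside by chance against 5 seen.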
